A study of Homo sapiens with 9 samples.

How the data were processed

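Messenger RNA was measured by sequencing in 9 libraries from tumours of Huh-7, a human hepatocellular carcinoma cell line, grown under the skin of immunodeficient NOD/SCID mice. Per the labels' protocols, adenovirus was injected into the established tumours on repeated days, RNA was captured with oligo(dT) beads, and the cDNA was made with random primers after fragmentation. The labels describe no step that keeps the strand. Whether reads of a gene and of its antisense partner were told apart is therefore not known. The 3 groups received an adenovirus carrying green fluorescent protein (Ad-GFP, the control), HNF4A (Ad-HNF4A) or HNF4A with the K458R change, lysine to arginine in its notation (Ad-K458R). Each group had 3 libraries. Groups were taken from the sample titles, and from the description of 1 Ad-K458R library whose title is misspelt. The separate treatment field counts upwards within the HNF4A and K458R groups as a spreadsheet fill would, and was not used for the groups. The labels number the tumours of a group but do not say that each came from a separate animal, so p-values measure the spread between these libraries.

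The authors deposited 1 table with raw read counts and FPKM for 50868 human Ensembl genes, per the file headers. Trimmomatic is named in the submitters' processing notes, while the aligner and the counting tool are not given in the sources used here. Those notes also name the mouse build mm10. The table holds human genes, however: 98.5% of its gene identifiers occur in GENCODE 29, and 94.8% of these have the identical position there on GRCh38. Positions below are those of the table. How reads of mouse cells in the tumours were treated is not given in the sources used here. Reads from mouse RNA that matched a human gene would be counted with it. The deposited FPKM equalled the count divided by the library total and by 1 length per gene for at least 99.99% of the genes compared in each library, within a relative tolerance of 0.0001. That length lay within 1% of the summed exons of GENCODE 29 for 10.8% of genes, so FPKM was used in an alternative test and not to compare genes with one another.

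The deposited counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) in R 4.3.3. The 9 libraries entered 1 fit with a term per group, TMM scaling and edgeR's filter on low counts, which left 16697 genes. TMM factors ran from 0.977 to 1.014. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05 with no limit on fold. Expression is given as CPM, the count relative to the TMM-scaled library total, as mean ± SD over 3 libraries. Standard errors (SE) of log2 fold changes were derived from the F statistic. Where the control libraries held no count of a gene, the fold is the mean of the other group over a floor of 3 counts in the control group. It is a lower bound for that mean only and takes no account of the spread between libraries. Where they held 1 to 3 counts, the ratio of counts is given with its exact 95% interval. Intervals and floors cover counting error only, since reads were not tagged by molecule.

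Before the data were examined, 40 gene lists, the designs, the alternatives and the rule for naming genes were fixed. The rule took HNF4A, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries (which chance gives to 10% of genes with 3 against 3), and up to 4 members with the smallest p from each list. In a comparison with fewer than 5 such genes it took the 10 with the smallest p. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, and lists with under 5 tested genes were not tested as a set. Overlap between the comparisons with the shared Ad-GFP libraries was set beside 20 simulated experiments without any effect. Alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), 3 other scalings, 2 other filters, fits of 6 libraries, a replicate block, a fold limit, and leaving out each library in turn. For lists they were an estimated correlation and fry. The list of liver transcription factors without HNF4A was added after seeing the data. Values of some single genes are not reported.

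Library totals ran from 15933702 to 23171796 counts, where 1 count corresponds to 0.0628 and 0.0432 CPM. The test was tried on simulated counts of 16697 genes, in which 50 well-expressed genes were given each of the known fold changes. In the comparison of Ad-HNF4A with Ad-GFP it called 40% of genes changed 1.5-fold, 76% of those changed 2-fold and 94% of those changed 4-fold. The figures were 44%, 90% and 100% for Ad-K458R against Ad-GFP, and 38%, 76% and 92% for Ad-K458R against Ad-HNF4A. False calls numbered 4, 11 and 10. Since the adjustment is stricter where few genes differ, these shares can be too high for a comparison with few calls. Genes with near-identical copies or shared exons (HSPA1A, TUBA3D, C4A, UGT1A1, ARL2-SNX15) and genes named by clone or antisense symbols are uncertain, as the handling of shared reads is not given in the sources used here.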

Results

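Huh-7 tumours that had received the control virus (Ad-GFP) were compared with tumours given Ad-HNF4A and tumours given Ad-K458R, by mRNA sequencing of 3 libraries in each group. Total counts were 18529618 to 23171796 with Ad-GFP, 15933702 to 19748918 with Ad-HNF4A and 17715527 to 22136627 with Ad-K458R. In a principal component analysis, Ad-HNF4A replicate 1 stood apart on the second component (12.7% of the variance), at 46.1 where the other libraries lay between -11.2 and 4.1. HNF4A is a nuclear receptor that governs many hepatocyte genes, and the series asks what its K458R change does in hepatocellular carcinoma.

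HNF4A mRNA (chromosome 20, 44355700 to 44434596, ENSG00000101076) was measured first, since both vectors carry it. It stood at 169 ± 14.4 CPM with Ad-GFP (SD, n = 3), 4200 ± 1040 CPM with Ad-HNF4A and 5300 ± 264 CPM with Ad-K458R. The log2 fold changes over Ad-GFP were 4.64 ± 0.18 (SE, adjusted p = 7.4e-06, edgeR) and 4.97 ± 0.18 (adjusted p = 4.1e-06). Within Ad-HNF4A the level was uneven, at 3700, 3510 and 5390 CPM in replicates 1, 2 and 3. Ad-K458R exceeded Ad-HNF4A by 0.34 ± 0.15 on the log2 scale, which did not pass the test (adjusted p = 0.59), although it was 0.56 and passed without Ad-HNF4A replicate 3 (adjusted p = 0.043). An exact two-sided permutation test of the 3 against 3 libraries gave p = 0.1 for each vector against Ad-GFP, the smallest it can give, and p = 0.2 between the vectors.

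**Figure D1:**
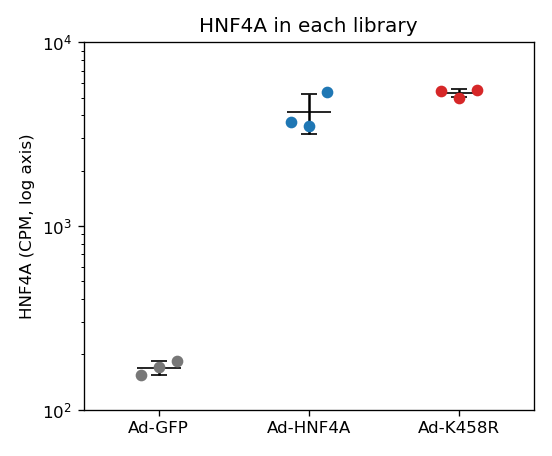
HNF4A mRNA in CPM, on a log axis, in the 3 libraries of each group. Points are libraries, the horizontal mark is the mean and bars are 1 SD; the Ad-GFP mean is 169 CPM, and Ad-HNF4A replicate 3 (5390 CPM) lies near the Ad-K458R mean of 5300 CPM.

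The 10 largest rises with Ad-HNF4A over Ad-GFP, among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, were of genes with 0 to 3 counts in the Ad-GFP libraries. SLC4A1, the anion exchanger of red cells and of the kidney, had no counts in the Ad-GFP libraries and 6.06 ± 1.84 CPM (SD, n = 3) with Ad-HNF4A, at least 126-fold higher. NR1I3, the nuclear receptor CAR, reached 4.33 ± 0.91 CPM (at least 90.3-fold), and G6PC, the catalytic subunit of glucose-6-phosphatase, reached 4.08 ± 2.27 CPM (at least 85.0-fold). TUBA3D and CEACAM20 were also without counts in the control and rose at least 71.2-fold and 44.9-fold, as did the clone-named AP000851.2, at least 87.0-fold. CYP1A2, a drug-metabolising cytochrome P450, rose from 0.0147 ± 0.0255 to 5.82 ± 0.995 CPM, a ratio of counts of 369 (95% interval 65.7 to 14600). BIN2, CORO2B and MOGAT2, the last an enzyme of triglyceride synthesis in the gut, had ratios of 349 (62.1 to 13800), 225 (39.8 to 8920) and 166 (56.4 to 808).

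In all, 527 genes were higher and 51 lower with Ad-HNF4A than with Ad-GFP among 16697 tested. Of the 527, 193 had a mean below 1 CPM in Ad-GFP. At least 2-fold changes numbered 297 higher and 3 lower. RBMS2, an RNA-binding protein gene (chromosome 12, 56521929 to 56596196), fell from 100 ± 5.14 to 25.3 ± 2.31 CPM, a log2 change of -1.99 ± 0.09 (SE, adjusted p = 8.4e-07, edgeR). TMEM30A, a subunit of phospholipid flippases, fell from 220 ± 3.47 to 134 ± 8.98 CPM (log2 change -0.71 ± 0.06, adjusted p = 6.6e-05). The heat shock gene HSPA1A fell from 64.7 ± 3.82 to 33.9 ± 3.0 CPM (adjusted p = 0.049). SLAIN1, PIGX, TNFAIP2, GBP1, F2RL2, TAF1A-AS1 and RP11-658F2.8 completed the 10 largest falls under the same limits on level and overlap, with log2 changes between -0.61 and -1.1. Outside those limits, the readthrough gene ARL2-SNX15 stood at 1.12 ± 0.468 CPM with Ad-GFP and had no counts with either vector (adjusted p = 0.015 with Ad-HNF4A and 0.012 with Ad-K458R). The lower genes numbered 14, 16 and 18 without Ad-GFP replicates 1, 2 and 3, and 29, 131 and 26 without Ad-HNF4A replicates 1, 2 and 3. Of the 51 lower genes, these fits called 10, 9, 10, 11, 35 and 10 again, so most single falls depend on the libraries used. The higher genes numbered 342 and 328 without Ad-GFP replicates 1 and 2, 333 without Ad-HNF4A replicate 3 and 407 without Ad-HNF4A replicate 1, and 333 in a fit of these 6 libraries alone.

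Among the lists of hepatocyte genes, gluconeogenesis and glycogen had 7 of 17 tested members higher and none lower (10 higher and 1 lower adjusted over the list alone). FBP1, a gluconeogenic phosphatase, rose from 3.83 ± 0.577 to 7.55 ± 1.33 CPM and PCK2 from 69.4 ± 1.01 to 88.8 ± 4.37 CPM. In the list of the urea cycle and amino acid breakdown, 6 of 26 members were higher (12 adjusted over the list alone). HPD, a tyrosine-degrading enzyme, rose from 4.77 ± 0.642 to 33.3 ± 3.2 CPM (log2 change 2.8 ± 0.12), and BHMT from 5.43 ± 0.802 to 19.1 ± 4.66 CPM, while the log2 change of ASS1, a urea cycle enzyme, was 1.07 ± 0.11. Bile acid genes were higher in 5 of 19 cases (8 adjusted over the list alone). CYP8B1, the sterol 12-hydroxylase, went from no counts to 1.69 ± 0.757 CPM, at least 35.2-fold, and BAAT, which conjugates bile acids, from 8.95 ± 1.46 to 20.1 ± 3.63 CPM. For drug metabolism the count was 5 of 28 (10 adjusted over the list alone), with NAT2 at 1.11 ± 0.16 and 2.69 ± 0.272 CPM. Apolipoproteins were higher in 6 of 20 cases (10 adjusted over the list alone): APOA4 rose from 18.6 ± 2.74 to 137 ± 23.9 CPM and APOA1 from 844 ± 26.3 to 1160 ± 138 CPM. Coagulation and complement had 5 of 29 members higher (5 adjusted over the list alone), SERPINC1 among them, and fatty acid oxidation 2 of 25 (7 adjusted over the list alone), ACAA1 among them.

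These 7 lists were called higher by camera, as were the liver transcription factors (5 of 23 higher and 1 lower, 5 and 2 adjusted over the list alone) and the macrophage markers (4 of 11 higher, 6 adjusted over the list alone), making 9. Camera did not call the plasma proteins of hepatocytes (1 of 23 higher, 2 adjusted over the list alone, adjusted p = 0.1). The transcription factor list was not called once HNF4A itself was left out of it (adjusted p = 0.19), a choice made after seeing the data. Mitochondrial genome mRNAs, S phase, mitosis, progenitor and epithelial-mesenchymal transition lists were called lower, with 1, 2, 0, 1 and 0 members called lower (5, 2, 0, 1 and 3 adjusted over the list alone). SNAI1, the 1 called member of the last list, was higher. The mitochondrial list was fixed as a check on library quality, and what moved it was not tested. The lists called lower numbered 3 without Ad-GFP replicate 1, 3 without Ad-HNF4A replicate 2 and 2 without Ad-HNF4A replicate 3. With an estimated correlation none of the 37 lists tested was called: adjusted p = 0.059 for gluconeogenesis and for macrophage markers, 0.11 for apolipoproteins, bile acid genes, the urea cycle and fatty acid oxidation, 0.16 for drug metabolism, transcription factors and progenitor markers, 0.25 for coagulation, 0.29 for mitochondrial mRNAs, 0.4 for epithelial-mesenchymal transition, 0.41 for S phase and 0.51 for mitosis. The test fry, which does not compare with other genes, called 13 lists higher and 2 lower.

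**Figure D2:**
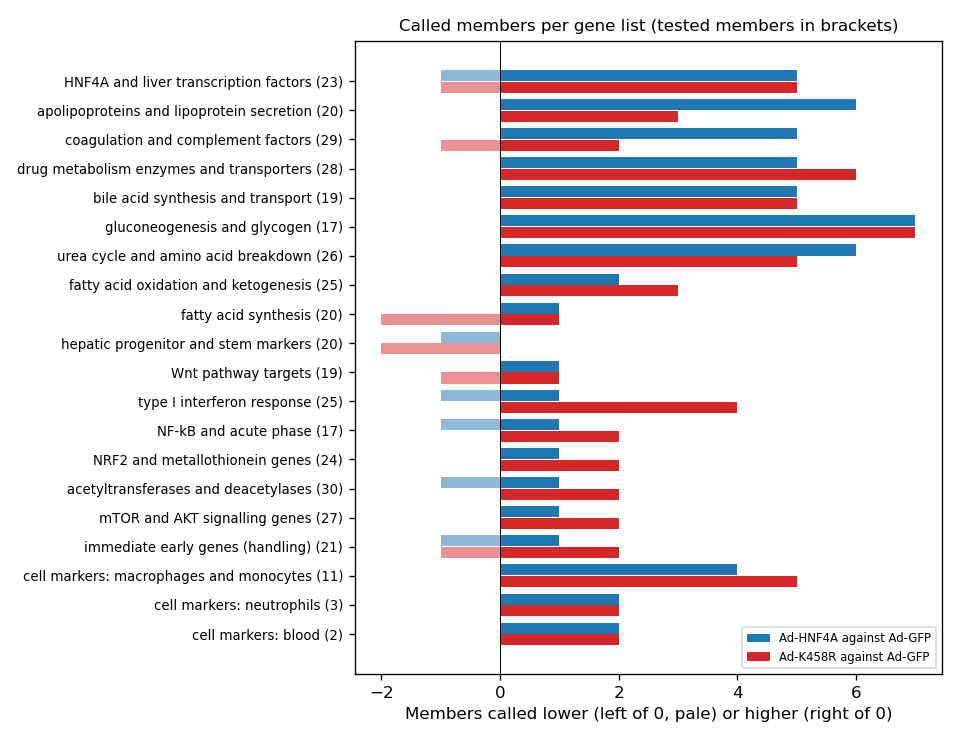
Number of members called higher (right of 0) or lower (left of 0, pale) at an adjusted p under 0.05 against Ad-GFP, for each gene list with at least 3 calls over both comparisons. Blue bars are Ad-HNF4A and red bars Ad-K458R, tested members are in brackets, and gluconeogenesis has 7 of 17 members higher in each.

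The 10 largest rises with Ad-K458R over Ad-GFP, by the same rule, were also of genes with few or no control counts. SLC4A1 reached 8.37 ± 0.83 CPM (SD, n = 3; at least 174-fold), CEACAM20 8.04 ± 0.328 CPM (at least 168-fold), NR1I3 7.28 ± 0.742 CPM (at least 152-fold) and G6PC 5.13 ± 2.37 CPM (at least 107-fold). TUBA3D and AP000851.2 rose at least 137-fold and 115-fold. BIN2, CYP1A2, TBX10 and CORO2B, with 1 control count each, had ratios of 469 (95% interval 83.7 to 18600), 451 (80.4 to 17800), 273 (48.6 to 10800) and 263 (46.7 to 10400).

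The totals were 555 genes higher and 39 lower, of which 340 and 4 changed at least 2-fold. RBMS2 fell to 24.9 ± 1.61 CPM (log2 change -2.01 ± 0.09, adjusted p = 5.7e-07, edgeR). SP3, a transcription factor gene on chromosome 2, fell from 150 ± 6.61 to 95.1 ± 6.28 CPM (-0.66 ± 0.07, adjusted p = 2.9e-04). ARMCX3 fell from 61.3 ± 2.91 to 33.0 ± 7.82 CPM and the orphan nuclear receptor NR4A2 from 27.1 ± 0.882 to 15.6 ± 4.41 CPM. AP002414.2, MBOAT4, RSBN1L, ARRDC3, SKA3 and C4orf46 were the other named falls, with log2 changes between -0.47 and -2.11. The lower genes numbered 10, 12 and 21 without Ad-GFP replicates 1, 2 and 3, and 14, 19 and 16 without Ad-K458R replicates 1, 2 and 3. Of the 39 lower genes, these fits called 6, 6, 11, 5, 12 and 6 again.

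Gluconeogenesis again had 7 of 17 members higher (8 adjusted over the list alone), with FBP1 at 9.1 ± 1.85 CPM and PCK2 at 87.8 ± 4.38 CPM. The counts were 5 of 26 for the urea cycle and amino acid breakdown (HPD 40.8 ± 3.06 CPM), 5 of 19 for bile acid genes (BAAT 36.8 ± 3.35 CPM), 6 of 28 for drug metabolism, 3 of 20 for apolipoproteins (APOA4 202 ± 11.8 CPM) and 3 of 25 for fatty acid oxidation. Adjusted over the list alone they were 8, 7, 9, 4 and 5. Type I interferon genes were higher in 4 of 25 cases (5 adjusted over the list alone). IFIH1, a sensor of double-stranded RNA, rose from 4.68 ± 0.223 to 10.3 ± 1.06 CPM and OAS1 from 14.3 ± 1.14 to 22.6 ± 2.09 CPM. With Ad-HNF4A their log2 changes were 0.84 and 0.4, and 1 of 25 members was higher and 1 lower. There the list was called higher by fry (adjusted p = 0.0098) but not by camera (adjusted p = 0.29). Between the vectors camera did not call it (adjusted p = 0.11). By camera 10 lists were higher with Ad-K458R, namely the 7 lists above, the macrophage markers, p53 targets and immediate early genes. Of the macrophage markers, 5 of 11 were higher (5 adjusted over the list alone). Among the p53 targets PLK3 rose, and among the immediate early genes FOSB and JUN rose and NR4A2 fell. With Ad-HNF4A the p53 targets were called higher by fry (adjusted p = 0.025) but not by camera (adjusted p = 0.49). Between the vectors camera did not call them (adjusted p = 0.12). With Ad-K458R camera called 3 lists lower, namely mitochondrial genome mRNAs, S phase and mitosis. They had 0, 0 and 1 members called (6, 0 and 1 adjusted over the list alone). The immediate early genes were fixed as a check on handling, and what moved them was not tested. Not called were coagulation and complement (2 of 29 higher, 1 lower, adjusted p = 0.97, camera) and plasma proteins (1 of 23 higher, adjusted p = 0.41). The liver transcription factors were not called either (5 of 23 higher, 1 lower, adjusted p = 0.37). By fry that list, which holds HNF4A itself, was called higher with Ad-HNF4A (adjusted p = 6.2e-05) and with Ad-K458R (adjusted p = 5.5e-05). Between the vectors camera did not call it (adjusted p = 0.83). Against Ad-GFP, the lists that camera called higher numbered 6 without Ad-K458R replicate 1, and those called lower 6 without Ad-GFP replicate 3. With an estimated correlation, gluconeogenesis (adjusted p = 0.044) and macrophage markers (adjusted p = 0.044) held. The others did not: adjusted p = 0.16 for bile acid genes, 0.19 for interferon genes, p53 targets and S phase, 0.22 for drug metabolism, fatty acid oxidation and immediate early genes, 0.28 for mitochondrial mRNAs, 0.3 for apolipoproteins and the urea cycle and 0.34 for mitosis.

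Some markers of other cell types moved with both vectors, but camera called only the macrophage list among them. The test fry also called the endothelium list higher with Ad-HNF4A (adjusted p = 0.044) and with Ad-K458R (adjusted p = 0.033). It called the fibroblast list higher with Ad-HNF4A (adjusted p = 0.046) but not with Ad-K458R (adjusted p = 0.15). No member of the skin keratinocyte list was called in either comparison. The endothelium, muscle and adipocyte lists had 1 member higher in each comparison, of 5, 6 and 4 tested. Of the macrophage list, CTSS rose from 3.22 ± 0.246 to 8.77 ± 0.779 and 9.27 ± 1.26 CPM with Ad-HNF4A and Ad-K458R (SD, n = 3), and LAPTM5 from 0.0979 ± 0.0102 to 0.94 ± 0.206 and 1.11 ± 0.152 CPM. COL6A1 of the fibroblast list rose from 11.6 ± 1.92 to 22.8 ± 5.26 and 26.4 ± 1.37 CPM while the list was not called (adjusted p = 0.49 and 0.78, camera). Neutrophil and blood lists had 3 and 2 tested members, too few for a set test, with LTF, S100A9, SLC4A1 and CD79A higher in both comparisons. The share of mitochondrial mRNA was 6.46 to 7.24% of counts with Ad-GFP, 5.64 to 5.91% with Ad-HNF4A and 5.58 to 6.19% with Ad-K458R.

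The 2 comparisons with Ad-GFP shared 398 higher genes, where 17.5 would be shared by independent lists of these sizes, and 4 lower genes, where 0.119 would be. No gene was called in opposite directions. Among the shared rises were HPD, BHMT, ASS1, APOA4 and CREB3L3, a hepatocyte transcription factor that stood at 64.3 ± 5.2, 120 ± 16.7 and 140 ± 6.14 CPM in the 3 groups (SD, n = 3). The shared falls were RBMS2, the liver transcription factor ONECUT2, and ARL2-SNX15 and PDE4D, this pair named after their values were seen. Without Ad-GFP replicates 1 and 3, Ad-HNF4A replicate 2 and Ad-K458R replicate 2 the shared lower genes numbered 2, 7, 9 and 2. Fold changes over all tested genes correlated at r = 0.875 across genes, which are not independent replicates. Simulated groups without effect that shared the control gave a mean r of 0.492. They shared a mean of 0.05 higher genes. Without an effect hardly any gene is called, so that count is no yardstick for the 398. The covariance was 0.3405, against 0.0379 simulated. The 3 control libraries are too few to split, so the part of the excess that comes from sharing them is not known beyond the simulation.

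**Figure D3:**
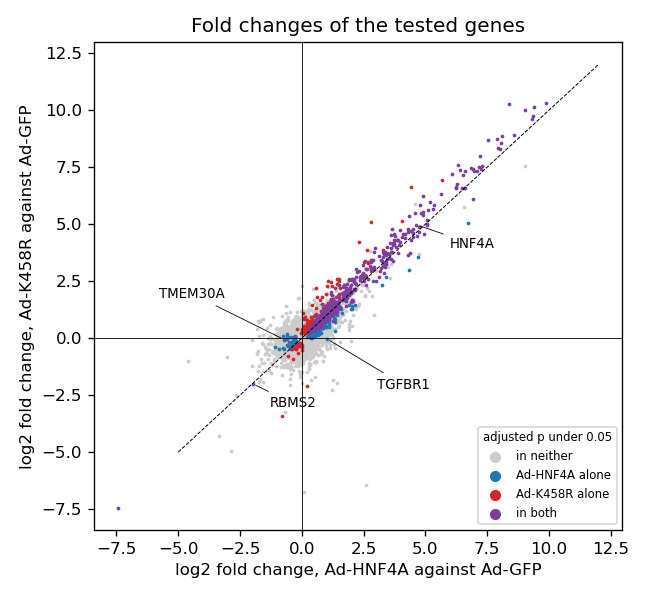
Log2 fold change of each of the 16697 tested genes with Ad-HNF4A (horizontal) and Ad-K458R (vertical), both against Ad-GFP. Colours mark genes called in neither, 1 or both comparisons, the dashed line marks equal fold changes, 398 genes are higher in both, and TGFBR1 and TMEM30A lie near the horizontal axis, at 1.02 and -0.71 with Ad-HNF4A and at -0.03 and -0.07 with Ad-K458R.

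Ad-K458R was then compared with Ad-HNF4A directly. TGFBR1, the type I receptor of TGF-beta (chromosome 9, 99104038 to 99154192, ENSG00000106799), stood at 48.0 ± 1.84 CPM with Ad-HNF4A and 23.2 ± 0.797 CPM with Ad-K458R (SD, n = 3), a log2 difference of -1.05 ± 0.08 (SE, adjusted p = 7.3e-04, edgeR). TMEM30A (chromosome 6, 75252924 to 75284968, ENSG00000112697) stood at 134 ± 8.98 and 210 ± 2.16 CPM, a difference of 0.64 ± 0.06 (adjusted p = 0.0023). These were the 2 genes called among 16697, and 1460 had an unadjusted p under 0.05. DESeq2 called 46 higher and 15 lower, and limma-voom 2 and 1. TGFBR1 and TMEM30A were called without each of the 6 libraries in turn, when the counts were 4, 4 and 11 higher and 4, 3 and 1 lower without Ad-HNF4A replicates 1, 2 and 3, and 1, 1 and 3 higher and 3, 2 and 5 lower without those of Ad-K458R. In the remaining genes with the smallest p, SP3 was at 136 ± 8.29 and 95.1 ± 6.28 CPM (adjusted p = 0.093), CEACAM20 at 2.15 ± 0.735 and 8.04 ± 0.328 CPM (adjusted p = 0.11), F2RL2 at 56.9 ± 9.1 and 92.5 ± 4.64 CPM (adjusted p = 0.13), CYP1A1 at 50.3 ± 1.83 and 76.3 ± 4.02 CPM (adjusted p = 0.16) and BAAT at 20.1 ± 3.63 and 36.8 ± 3.35 CPM (adjusted p = 0.19). DCAF5, LAMP3 and PIGX had adjusted p between 0.17 and 0.19. In simulated counts, with 50 well-expressed genes changed at each fold, the test called 38% of genes that differed 1.5-fold. The adjustment is stricter where few genes differ, so that share can be too high here. CEACAM20 differed 3.69-fold and BAAT 1.83-fold without passing, so smaller differences and some larger ones could go uncalled.

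No member of any list passed the test between the vectors by edgeR over all genes. Adjusted over the list alone, 5 members of fatty acid synthesis were lower and 4 of NF-kB and acute phase higher with Ad-K458R, and none of the plasma proteins. As sets, camera called 9 lists lower with Ad-K458R, with fatty acid synthesis (adjusted p = 3.5e-05) and plasma proteins (adjusted p = 5.9e-04) first, and 4 higher: epithelial-mesenchymal transition, NF-kB and acute phase, NRF2 and metallothionein, and immediate early genes. Without Ad-HNF4A replicate 3, 3 lists were lower. None held with an estimated correlation, where the adjusted p ran from 0.32 for fatty acid synthesis to 0.48 for the urea cycle list, with 0.33 for plasma proteins. Median log2 differences were small, at -0.16 for fatty acid synthesis, -0.15 for plasma proteins and 0.3 for NF-kB and acute phase.

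**Figure D4:**
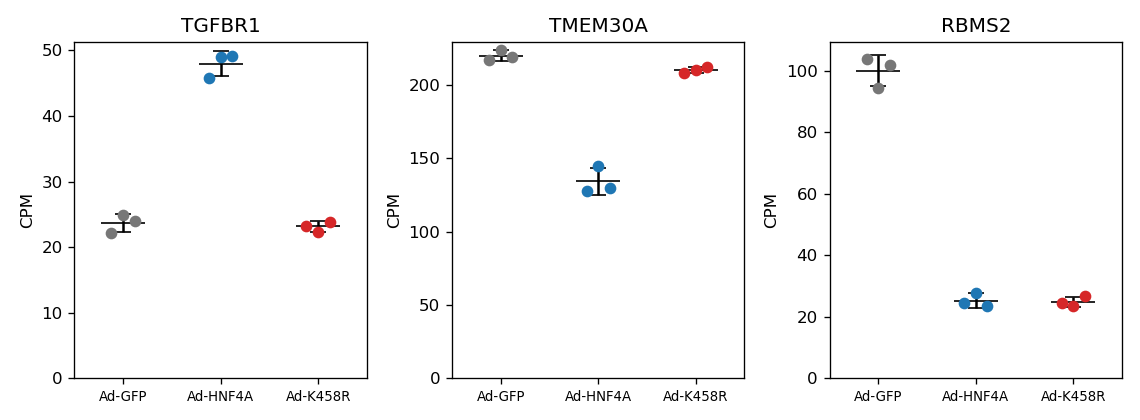
Levels in CPM of TGFBR1, TMEM30A and RBMS2 in the 3 libraries of each group, with the mean and 1 SD. TGFBR1 averages 48.0 CPM with Ad-HNF4A and 23.2 CPM with Ad-K458R, TMEM30A 134 and 210 CPM, while RBMS2 lies at 25.3 and 24.9 CPM against 100 CPM with Ad-GFP.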

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

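The tests of neighbouring genes and of macrophage genes below were chosen after the results were seen. TGFBR1 and TMEM30A were singled out because the effects of the 2 vectors on them differed by a direct test. TGFBR1 rose with Ad-HNF4A over Ad-GFP (log2 change 1.02 ± 0.08, SE) and was near its control level with Ad-K458R (-0.03 ± 0.08), a difference of -1.05. TMEM30A changed by -0.71 ± 0.06 and -0.07 ± 0.06, a difference of 0.64. A regional copy number change in the Ad-HNF4A tumours is argued against for TGFBR1. The 13 tested genes within 1 Mb of it had a median difference of 0.022 ± 0.049 (SE) and ran from -0.27 to 0.17. For TMEM30A the argument is weaker: its 6 neighbours had a median of -0.002 ± 0.155 but ran from -0.29 to 0.53. A copy number change limited to either gene was not tested. Neither difference hinged on 1 library. It came no closer to 0 than -1.02 for TGFBR1 and 0.61 for TMEM30A when each of the 6 libraries was left out. The adjusted p (edgeR) was then at most 0.013 and 0.016. Both genes were picked for passing the test in these same libraries, so this is not independent support. A direct effect of the K458R change remains open as a hypothesis, as do differences between the virus preparations, which the design ties to the groups.

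The macrophage marker list was called higher with both vectors, and with an estimated correlation for Ad-K458R (adjusted p = 0.044) but not for Ad-HNF4A (adjusted p = 0.059). RNA from macrophages is left open as a source, since the answer turns on which other macrophage genes are counted. The 4 members called in both comparisons (CSF1R, CTSS, FCER1G, LAPTM5) rose together by 8.2 ± 0.429 CPM (SE, on library totals). A set of 13 other macrophage genes rose by 0.641 ± 0.541 CPM, all 19 others of both lists by -13.5 ± 18.1 CPM, and the 18 below 100 CPM in Ad-GFP by 11.6 ± 2.22 CPM, most of it from CD68, which the control tumours already expressed (12.4, 17.9 and 24.8 CPM in the 3 groups), while C1QA, C1QB, C1QC and CYBB had 1 to 3 counts over all 9 libraries. TYROBP, by contrast, had no counts with Ad-GFP, 1, 6 and 4 with Ad-HNF4A and 7, 6 and 13 with Ad-K458R. The sets of 19 and 18 genes differ by LYZ alone, at 4297 to 7018 counts per library. Macrophages of the host would be mouse cells, whose transcripts reach the human gene counts to an unknown degree. Induction in the tumour cells themselves was not tested.

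As sets, 13 lists differed between the vectors at the preset correlation. Lower with Ad-K458R were fatty acid synthesis (adjusted p = 3.5e-05), plasma proteins (5.9e-04), ribosomal proteins (0.0012), cholesterol synthesis (0.0034), coagulation and complement (0.0035), oxidative phosphorylation (0.0056), S phase (0.013), apolipoproteins (0.025) and the urea cycle with amino acid breakdown (0.048). Higher were epithelial-mesenchymal transition (1.5e-04), NF-kB and acute phase (1.5e-04), NRF2 and metallothionein genes (0.0012) and immediate early genes (0.046). Without Ad-HNF4A replicate 3 the lower lists numbered 3 and not 9. None was called with an estimated correlation or with fry.

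Splits of the samples were counted for each comparison. Among the 10 splits of 6 libraries into 3 and 3, 1 split (the real one) gave as many calls in fits of those libraries alone: 351 genes against a highest other of 9 for Ad-HNF4A and Ad-GFP, 632 against 6 for Ad-K458R and Ad-GFP, and 9 against 8 for Ad-K458R and Ad-HNF4A. The 10 splits are too few for a share under 0.05.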

How the results depend on the processing

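The list of liver transcription factors without HNF4A was the 1 alternative chosen after seeing the data; the numbers of lists called were then 8 higher and 5 lower for Ad-HNF4A against Ad-GFP, 10 and 3 for Ad-K458R against Ad-GFP and 4 and 9 for Ad-K458R against Ad-HNF4A. No result changed direction while called. For Ad-HNF4A against Ad-GFP (527 genes higher, 51 lower), the higher genes numbered 255 by limma-trend on FPKM, 333 with only the 6 libraries of the comparison and 297 at 2-fold or more, and the lower genes 81 with no filter on low counts, 22 with a replicate block, 132 by DESeq2, 9 by limma-trend, 18 with 6 libraries and 3 at 2-fold. For Ad-K458R against Ad-GFP (555 and 39), the higher genes numbered 286 by limma-trend and 340 at 2-fold, and the lower genes 20 with library totals only, 15 with a block, 89 by DESeq2, 7 by limma-trend and 4 at 2-fold. For Ad-K458R against Ad-HNF4A (1 and 1), the higher genes numbered 7 with no filter, 46 by DESeq2, 2 by limma-voom, 3 by limma-trend, 6 with 6 libraries and 0 at 2-fold, and the lower genes 2 with no filter, 15 by DESeq2, 2 by limma-trend and 3 with 6 libraries; TGFBR1 and TMEM30A were called in each of these but for TMEM30A at 2-fold. Genes shared by the comparisons with Ad-GFP (398 higher, 4 lower) numbered 259 and 2 at 2-fold, and DESeq2 gave 12 lower. Lists called with an estimated correlation numbered 0 higher and 0 lower, 2 and 0, and 0 and 0 in the 3 comparisons. By fry 2 lists were lower for Ad-HNF4A against Ad-GFP, and 0 were higher and 0 lower between the vectors. The fold limit lowers counts by construction, and the cause was not tested for the others. Fewer libraries did not always lower counts. Fits of 6 libraries gave 577 higher and 55 lower for Ad-K458R against Ad-GFP. The labels do not say whether replicate numbers pair the libraries, and no large effect shared by a number was seen. The 9 correlations between libraries of 1 number, of deviations from the group means, ran from -0.038 to 0.053. With 1 library left out, the higher and lower genes ran from 328 to 625 and 14 to 131 for Ad-HNF4A against Ad-GFP, 377 to 435 and 10 to 21 for Ad-K458R against Ad-GFP, and 1 to 11 and 1 to 5 between the vectors. The HNF4A difference between the vectors ran from 0.22 to 0.56, the shared genes from 284 to 406 higher and 2 to 9 lower, lists higher from 7 to 9, 6 to 10 and 3 to 5, and lists lower from 2 to 5, 3 to 6 and 3 to 9. Over the genes named and all alternatives but the fold limit, the call was the same in 2344, 2382 and 2545 cases in the 3 comparisons, lost in 243, 233 and 0 and gained in 66, 39 and 31. The same call includes genes called in neither fit, and genes not tested in an alternative were left out. Between the vectors only TGFBR1 and TMEM30A had a call to lose. Depth limits genes near 0 counts in Ad-GFP, whose folds are bounds or ratios with wide intervals.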

Other observations

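No test in this part was chosen after its result was seen. Genes of other HNF4A-expressing epithelia were looked at because several genes that were near silent with Ad-GFP are known from the gut or kidney; the 3 lists below were written after those results and before the values of their members were seen. In a list of intestinal epithelium genes, CDHR2, a brush border cadherin, rose from 13.6 ± 1.81 CPM with Ad-GFP to 44.1 ± 9.18 with Ad-HNF4A and 44.5 ± 3.63 with Ad-K458R (SD, n = 3), CDHR5 from 8.84 ± 0.546 to 21.3 ± 2.92 and 15.1 ± 2.71 CPM, and EPS8L3 from 71.9 ± 5.94 to 100 ± 7.1 and 96.9 ± 6.89 CPM. AOC1 was higher in both as well. In all, 5 of 27 tested members were higher with Ad-HNF4A and 4 with Ad-K458R. In a list of kidney proximal tubule genes, SLC3A1, a cystine transporter subunit, rose from 5.76 ± 0.137 to 11.8 ± 1.2 and 14.2 ± 0.753 CPM, and ACY3 from 27.3 ± 3.83 to 47.0 ± 8.6 and 44.6 ± 4.59 CPM, with 2 and 3 of 17 members higher. Of 13 tested neuronal genes, a control list, none was called.

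A candidate explanation is that HNF4A raised genes of these epithelia as sets. Of the called members, AOC1 (0.102 CPM) and PAX8 (0.734 CPM) were low with Ad-GFP and the others stood at 5.76 to 71.9 CPM, so the lists say little about the genes that were near silent. Camera called both lists at the preset correlation, but with an estimated correlation the larger p of the 2 comparisons was 0.26 for the intestinal list and 0.16 for the kidney list, so the question is open. For the neuronal list it was 0.76. Some members are expressed in liver too.

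Genes called higher with the mean of both vectors over Ad-GFP (652 without HNF4A) tended to stand higher with Ad-K458R than with Ad-HNF4A: the median log2 difference was 0.087 and 64% were above 0. The 1 gene called between the vectors among them, TGFBR1, was lower with Ad-K458R. The mean log2 level of these genes was 3.025, 2.91 and 3.175 in Ad-HNF4A replicates 1, 2 and 3 and 3.221, 3.157 and 3.177 in those of Ad-K458R, a group difference of 0.148 (exact permutation p = 0.2, smallest possible 0.1). The amount of delivered HNF4A mRNA may account for it. Ad-HNF4A replicate 3 had as much HNF4A as the Ad-K458R libraries (12.4 against 12.29 to 12.42 log2 CPM) and a like level of the induced genes. Over the 6 libraries Pearson's r was 0.96 (exact permutation p = 0.0042, adjusted 0.017) and Spearman's rho 0.94 (p = 0.017, adjusted 0.033), among 4 relations computed; without the 2 libraries farthest from the median HNF4A level r was 0.57, so the relation rests largely on Ad-HNF4A replicates 1 and 2. With the group means taken out, Pearson's r was 0.93 and Spearman's rho 0.89 (exact permutation p = 0.056 each, adjusted 0.056), which misses 0.05, and dose and protein variant cannot be told apart with 3 libraries each.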
